A study of Mus musculus with 20 samples.

How the data were processed

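RNA was measured by sequencing in BaF3 cells, a mouse pro-B cell line that depends on the cytokine IL3 for growth. Per the labels, the cells overexpressed the thrombopoietin receptor together with wild-type calreticulin (WT), a Type1 or a Type2 calreticulin mutant, or carried JAK2VF with the receptor. Each line was taken with IL3 at 2 ng/mL (unstarved) or after 24 h without it (starved). There were 3 replicates in each of the 6 calreticulin groups and 1 library per condition of JAK2VF, 20 libraries in all. The replicates are not said to be separate cultures, so every p-value measures only the spread between these samples, which may be technical. Each genotype is a line of its own, so genotype and line cannot be told apart.

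The deposited values are whole-number counts of reads per gene, not normalised, for 47643 genes. Per the labels' protocols, total RNA was sequenced as paired-end reads of 100 bp on a NovaSeq 6000, and the reads of 2 flow cells were combined per sample before the authors counted them. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.3, mapped with STAR 2.7.5b to the mouse build GRCm38.p4 and counted with featureCounts 1.6.4 on Galaxy 20.05. DESeq2 1.22.1 is listed among the tools. The release of the GENCODE annotation and the strand setting of the counting are not given in the sources used here. Reads that map to several places are shared or lost in ways that the counts do not record, which affects the globin genes, the T cell receptor gamma segments and other close paralogs. Without a known strand setting, an antisense gene cannot be separated from its partner. Mitochondrial, nuclear noncoding and ribosomal transcripts enter the library totals, so their share changes the counts left for other genes.

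Gene symbols came from a table of gene identifiers, in which 47224 of the 47643 identifiers had a symbol and 39106 also matched by version. Coordinates are those of GRCm38. There were 17569 genes with no count in any library. Depth ran from 14793588 to 69470077 counts per library. Genes were kept by edgeR's filterByExpr on the 18 calreticulin libraries (17836 genes), and libraries were scaled by the trimmed mean of M values (TMM). Counts were tested with edgeR 4.0.16's quasi-likelihood test in R 4.3.3, 2-sided, with the 6 groups as the only terms and 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The common dispersion was 0.0941, a biological coefficient of variation of 0.307. The interaction tests compared the starved minus unstarved difference between genotypes. Log2 fold changes (log2FC) are given with their standard error (SE), and levels as CPM, counts scaled to a common library total after TMM, mean ± SD. Replicates of one group differed by far more than sampling noise, with a chi-square per degree of freedom of 47.9 to 581 over 18 pairs, so none were merged.

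The tests were run on simulated counts with 200 genes changed before the filter. It left 17460 genes, with not all of the 200 among them. For starved Type1 against WT, 2 of 67 genes changed 1.5-fold were recovered, 14 of 67 at 2-fold and 47 of 64 at 4-fold, with 5 wrong calls. For the interaction of Type1 against WT the numbers were 0 of 67, 3 of 67 and 36 of 64, with 3 wrong calls. Small changes were therefore mostly not detectable in the fit without the replicate block, the one simulated, least of all in the interactions.

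The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. There were 26 lists: XBP1 targets, ATF6 targets, PERK-ATF4-CHOP targets, RIDD substrates (RNAs degraded by IRE1), ER calcium handling, STAT5 targets, ERK targets, the anti-apoptotic and pro-apoptotic BCL2 families, FOXO targets, p53 targets, DNA replication, mitosis, ribosome biogenesis, cholesterol synthesis, glycolysis, oxidative phosphorylation, autophagy and lysosome, interferon response, cytosolic heat shock, MHC class I presentation, and markers of megakaryocytes, pro-B cells, myeloid cells, mast cells and basophils, and erythroid cells. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, 2-sided and adjusted over the 26 lists of a comparison. The same test was run with an estimated correlation. Members of a list were also counted with p adjusted over the list alone. Genes named are the transgene loci Calr, Mpl and Jak2, then the 8 largest rises and falls (4 in the secondary comparisons) among genes past the threshold, at least 2-fold changed, with a mean log2 CPM of at least 2 and groups that did not overlap. They also include the 4 members with the smallest p of each called list and 2 of each other list, and 18 genes fixed by name. The rankings by size left out ribosomal protein, histone and mitochondrially encoded genes. Also left out were symbols of Gm, AC, AL or BC with digits, those ending in Rik or -ps, and genes without a symbol. Any other gene is said to be chosen after its values were seen.

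The replicate numbers of the labels were checked for pairing from the correlation of deviations from group means. Every same-numbered pair had a correlation over 0.1 in the 6 comparisons between genotypes (lowest 0.134, highest 0.814) and in Type2 starvation (0.104 to 0.466), so there the numbers were taken as pairing the samples. This rests on the data, since the labels do not say what a number shares. In WT starvation (-0.0931 to 0.272) and Type1 starvation (0.00815 to 0.29) they were not, nor in the interactions, each of which holds the groups of 1 or both of these. Fits with the number as a block are given where they change a call. The block gave each number 1 effect over all 18 libraries, the same in starved and unstarved cells, and did not pair the compared libraries alone. Its values assume an effect shared across starvation, which was not found for every pair in WT and Type1 starvation.

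The JAK2VF pair has no replicate, and only log2 ratios of CPM + 1 are given, for genes with at least 5 CPM in at least 1 library. List medians were placed among 10000 random lists matched on expression. Alternatives were another scaling (median-of-ratios factors, or total library size), no filter or a stricter filter (at least 50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, a fit of only the compared groups, the replicate block, and leaving out each library in turn. Using replicates 1 and 2 only, a block without WT starved replicate 2, a block with an estimated correlation, and the lists other than XBP1 and STAT5 under each alternative were added after seeing the data. Total library size moved the median of all genes in starved Type1 against WT to 0.13, in starved Type2 against WT to 0.14, in starvation of Type1 to 0.16 and of Type2 to 0.13. The interaction medians moved to 0.20 for Type1 and 0.19 for Type2, where TMM left the medians between -0.020 and 0.043. Fold changes are relative to the TMM scale. Intervals and floors cover counting error only.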

Results

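The libraries held between 14793588 and 69470077 counts. WT starved replicate 2 was the shallowest, and the next was WT starved replicate 1 with 43169671. WT starved replicate 2 also stood apart in other measures. The long noncoding RNA Gm26917 took 14.6% of its counts, mitochondrial genes 7.76% and the 10 most abundant genes 30.7%, and 19697 genes had a count, against 21689 to 23076 in the other libraries. Mitochondrial genes took 4.27% and 5.04% in the other WT starved libraries, 1.40% to 2.29% in Type1 starved, 1.60% to 2.81% in Type2 starved and 0.712% to 1.38% in unstarved calreticulin libraries. The principal components of the calreticulin libraries held 42.7% and 21.3% of the variance, and replicate 3 lay apart from replicates 1 and 2 in every group. On the first component WT and Type1 unstarved replicates 2 lay at -13.1 and -17.4. The other unstarved libraries lay at -82.5 to -35.1 and the starved ones at 22.0 to 99.7.

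The loci of the transgenes were read in every group. Jak2, the kinase of the thrombopoietin receptor, stood at 855 CPM in unstarved and 846 CPM in starved JAK2VF cells, against group means of 164 to 242 CPM in the calreticulin groups (n = 3 each). Calr, an ER chaperone, had 1372 ± 251 CPM in WT, 1434 ± 373 in Type1 and 1367 ± 203 in Type2 unstarved cells, and 849 ± 431, 1046 ± 85.6 and 848 ± 125 CPM in starved cells. Mpl, the receptor for thrombopoietin, had 7.20 ± 3.20, 5.00 ± 2.35 and 6.49 ± 0.918 CPM unstarved. In starved cells it had 30.2 ± 36.6, 9.39 ± 2.35 and 19.4 ± 10.5 CPM. The species and sequence of the introduced Calr and Mpl copies are not given in the sources used here, and reads of a foreign copy need not count to the mouse gene. These values therefore do not check the labels of the calreticulin lines. Between starved lines none of these genes passed the test, with log2FC for Type1 against WT of 0.24 ± 0.31 for Calr (edgeR adjusted p = 0.749), -1.75 ± 0.69 for Mpl (0.215) and -0.07 ± 0.20 for Jak2 (0.897). For Type2 against WT they were -0.06 ± 0.31 (0.976), -0.69 ± 0.68 (0.818) and -0.18 ± 0.20 (0.847). Mpl had 72.2 CPM in WT starved replicate 2 against 12.4 and 5.91 CPM in the others. Without that library its log2FC turned to 0.04 for Type1 and 1.09 for Type2 against WT, and those of Calr to 0.75 and 0.46, none past the test.

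Starved and unstarved WT cells were compared for what IL3 withdrawal changes without a calreticulin mutation. All 26 DNA replication genes fell, among them Rrm2, a ribonucleotide reductase subunit (log2FC -3.16 ± 0.27), and Ccne2, a cyclin of S phase entry (-2.94 ± 0.25). Ung, a uracil glycosylase, had -4.32 ± 0.56. Sqle and Ldlr, of sterol synthesis and uptake, fell too (-2.24 ± 0.17 and -2.78 ± 0.28). The 9 of 17 STAT5 targets that fell included Pim1, a survival kinase (-2.46 ± 0.32), Id1, an inhibitor of differentiation (-3.62 ± 0.45), Myc (-1.76 ± 0.35) and the feedback inhibitor Cish (-1.78 ± 0.57). Bcl2, which blocks apoptosis, fell (-1.09 ± 0.30), whereas Bcl2l11, which encodes the death inducer BIM, rose (2.04 ± 0.34, adjusted p = 5.56e-04), as did Bid (1.06 ± 0.17). The largest falls were Tcrg-C1 (-6.39 ± 0.63), Trgj1 (-5.84 ± 0.70), Serpina3f (-4.87 ± 1.22), the Fc receptor Fcgr1 (-4.40 ± 0.82), Ung, Nxpe5 (-4.20 ± 0.33), Serpina3g (-4.05 ± 0.72) and Trgj2 (-3.80 ± 0.69). The largest rises were the embryonic globin Hba-x (5.47 ± 1.41), the mucin Muc6 (4.04 ± 0.75), Serpine1 (4.04 ± 0.83), Mroh6 (3.90 ± 0.78), Hbb-bh1 (3.62 ± 1.26), Hbb-bt (3.31 ± 0.89), Nt5e (3.17 ± 0.67) and Hba-a1 (3.05 ± 0.86). The T cell receptor gamma segments, the globins and the Serpina3 genes have close copies, so reads can be split among them. In all, 5270 of 17836 genes changed by edgeR's quasi-likelihood test, 2459 higher and 2811 lower, and 2923 changed at least 2-fold (n = 3 against 3). Without WT unstarved replicate 3 the count was 3089. Of 36 named genes called here, 30 kept the call whichever library was left out. Hbb-bh1 lost it without WT unstarved replicate 1 (adjusted p = 0.0928) or 2 (0.109) or WT starved replicate 1 (0.0931), 2 (0.0553) or 3 (0.0609), and Hbb-bt without WT unstarved replicate 3 (0.0566). Hba-a1 lost it without WT starved replicate 1 (0.0578) or unstarved replicate 3 (0.0663), and Cish without starved replicate 1 (0.0562) or 3 (0.0907) or unstarved replicate 1 (0.0725) or 3 (0.121).

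By list, all 26 DNA replication genes fell in starved WT cells, with a median log2FC of -2.24 (camera adjusted p = 4.4e-34), and all 26 fell when adjusted over the list alone. Among 21 cholesterol synthesis genes 17 fell (18 adjusted over the list alone, median -1.45, adjusted p = 2.97e-19), among 24 ribosome biogenesis genes 21 fell (23, median -1.02, adjusted p = 2.59e-11), among 20 mitosis genes 15 fell (16, median -1.21, adjusted p = 1.2e-07), and among 17 glycolysis genes 11 fell (12, median -1.35, adjusted p = 4.4e-07). Oxidative phosphorylation (13 of 20 fell; 13 adjusted over the list alone, median -0.68, adjusted p = 3.94e-05) and cytosolic heat shock (6 of 8; 6, median -1.05, adjusted p = 0.00343) were also lower. ERK targets had 9 falls and 1 rise among 14 genes (9 and 2 adjusted over the list alone, median -1.31, adjusted p = 5.96e-05), and STAT5 targets 9 falls among 17 (10 falls and 1 rise, median -0.87, adjusted p = 4.24e-05). Genes of the unfolded protein response were lower as well: 18 of 28 XBP1 targets fell (19 adjusted over the list alone, median -0.66, adjusted p = 2.24e-05) and 11 of 14 ATF6 targets (11, median -1.09, adjusted p = 1.38e-06). Among them were Hspa5, the chaperone BiP (-1.80 ± 0.29), Manf, a secreted ER stress protein (-1.66 ± 0.23), Ssr1 of the translocon (-1.37 ± 0.22) and Xbp1 itself (-0.64 ± 0.19, adjusted p = 0.0213). The call of Xbp1 was lost without WT unstarved replicate 3 (0.120) or starved replicate 3 (0.0528). Ern1 (log2FC 0.76, edgeR adjusted p = 0.155) and Dnajb9 (0.16, 0.767), also XBP1 targets, did not pass. Autophagy and lysosome genes had 5 rises among 21 (4 adjusted over the list alone, median 0.65, adjusted p = 0.0165), MHC class I presentation 4 among 12 (5, median 0.53, adjusted p = 0.0155) and erythroid markers, mostly globins, 4 among 9 (5, median 2.40, adjusted p = 0.00841). Without WT unstarved replicate 3 the autophagy list (median 0.37, adjusted p = 0.157) and the MHC list (0.35, adjusted p = 0.0501) lost their calls. All 14 calls were lost with an estimated correlation (adjusted p from 0.139 to 0.576 with an estimated correlation). The mitochondrial share given above was also higher in these starved libraries than in the unstarved ones.

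The other 12 lists were not called in starved against unstarved WT cells. ER calcium handling had 6 rises, among them the calcium channel Itpr2 (1.52 ± 0.39), and 3 falls (7 and 3 adjusted over the list alone, median 0.37, adjusted p = 0.318). PERK-ATF4-CHOP targets had 5 falls (3 adjusted over the list alone, median -0.19, adjusted p = 0.14), and no RIDD substrate passed (0 adjusted over the list alone, median 0.12, adjusted p = 0.482). Only 5 of the 9 RIDD substrates were measured, without Scara3, Sparc, Pmp22 and Pdgfrb. The anti-apoptotic BCL2 family had 1 fall, Bcl2 (1 adjusted over the list alone, median -1.09, adjusted p = 0.14), and the pro-apoptotic family 2 rises and 1 fall (2 and 1, median 1.06, adjusted p = 0.14). FOXO targets had 3 rises and 1 fall (3 and 1 adjusted over the list alone, median 0.46, adjusted p = 0.205), p53 targets 2 rises (2, median 0.49, adjusted p = 0.14) and the interferon response 2 rises and 1 fall (2 and 1, median 0.21, adjusted p = 0.14). Megakaryocyte markers had 5 rises and 1 fall among 13 (5 and 1 adjusted over the list alone, median 0.58, adjusted p = 0.14). The transcription factors Runx1 (1.17 ± 0.27) and Nfe2 (1.18 ± 0.29) rose. Mpl was called too (2.12 ± 0.70, adjusted p = 0.0325), a call lost without WT starved replicate 2 (0.687) or unstarved replicate 1 (0.0659) or 3 (0.130). Pro-B cell markers had 1 rise among 4, Vpreb1 of the surrogate light chain (2.33 ± 0.56; 1 adjusted over the list alone, median 0.34, adjusted p = 0.386). These 4 were the only ones measured of 15, without Cd19, Pax5, Ebf1, Rag1, Rag2 and Il7r among others. Myeloid markers had 1 rise among 11 (0 adjusted over the list alone, median 0.32, adjusted p = 0.753) and mast cell and basophil markers 1 among 7 (0, median 0.74, adjusted p = 0.181).

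IL3 withdrawal was then read in each mutant line. In Type1 cells the globins Hba-x (7.25 ± 1.65), Hba-a1 (4.56 ± 0.92), Hbb-bs (4.42 ± 1.05) and Hbb-bt (4.03 ± 0.93) rose most, and Serpina3f (-4.59 ± 1.16), Tcrg-C1 (-4.17 ± 0.55), Trgj1 (-3.93 ± 0.58) and Il2ra, the IL2 receptor alpha chain (-3.60 ± 0.87), fell most. In Type2 cells Hba-x (7.51 ± 1.64), Hbb-y (5.84 ± 1.44), Hba-a1 (5.22 ± 0.95) and Hbb-bs (5.03 ± 1.08) rose most, and Serpina3f (-6.55 ± 1.33), Tcrg-C1 (-4.68 ± 0.56), Trgj1 (-4.24 ± 0.59) and Slfn2 (-3.67 ± 0.65) fell most. Hbb-bs lies on chr 7 from 103826534 to 103828096, in the beta-globin cluster, where reads can be shared. Rrm2 fell in Type1 (-1.60 ± 0.25) and Type2 (-1.99 ± 0.25), and so did Sqle (-1.38 ± 0.16 and -1.55 ± 0.16). Xbp1 fell in both lines (-0.94 ± 0.19 and -1.07 ± 0.19), and so did Hspa5 (-1.17 ± 0.28 and -1.62 ± 0.29). Edem1, which takes misfolded proteins out of the ER, fell in Type1 (-0.74 ± 0.12). Bcl2 did not pass in Type1 (-0.29 ± 0.29, adjusted p = 0.579) or in Type2 (-0.68 ± 0.30, 0.119; 0.00502 with the replicate block). Bcl2l11 rose in Type2 (1.56 ± 0.33) and had a log2FC of 1.16 ± 0.33 in Type1 (adjusted p = 0.052).

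In Type1 starvation 891 genes changed (410 higher, 481 lower; 539 at least 2-fold), and in Type2 starvation 3112 (1413 higher, 1699 lower; 1553 at least 2-fold), or 4914 with the replicate block. Scaled by total library size the splits became 445 higher and 177 lower in Type1, 1511 and 895 in Type2 and 1815 and 2971 in WT. Of the WT calls 846 were shared with Type1 and 2664 with Type2, and Type1 and Type2 shared 845, with 0 genes opposite in any pair. These 3 comparisons use different libraries. XBP1 targets fell for 5 of 28 genes in Type1 (15 adjusted over the list alone, median -0.55, adjusted p = 7.43e-08) and 17 in Type2 (21; -0.75, adjusted p = 5.8e-09). DNA replication genes fell for 9 of 26 in Type1 (24 adjusted over the list alone, median -1.04, adjusted p = 2.15e-16) and 21 in Type2 (25; -1.25, adjusted p = 1.79e-19), and cholesterol synthesis genes for 11 of 21 in Type1 (19; -1.02, adjusted p = 4.16e-18) and 15 in Type2 (17; -1.17, adjusted p = 8.22e-18). STAT5 targets had 6 falls in Type1 (8 falls and 1 rise adjusted over the list alone, median -0.85, adjusted p = 7.77e-07) and 8 falls and 1 rise in Type2 (10 and 1; -0.996, adjusted p = 8.01e-06). Erythroid markers rose for 4 of 9 genes in Type1 (5 adjusted over the list alone, median 1.60, adjusted p = 5.88e-06) and 6 in Type2 (7; 4.25, adjusted p = 6.1e-05). In each line 15 of 26 lists were called, 3 higher and 12 lower in Type1 and 2 and 13 in Type2. With an estimated correlation camera called 0 of the 26 lists in either line. The 10 calls given here then had adjusted p from 0.121 to 0.189. Mitochondrial genes took 1.40% to 2.29% of counts in starved and 0.71% to 1.04% in unstarved Type1 libraries, and 1.60% to 2.81% and 0.79% to 0.89% in those of Type2. The Type1 count depended on single libraries: it was 152 without Type1 unstarved replicate 1, 2016 without unstarved replicate 2, 242 without unstarved replicate 3, and 189, 442 and 356 without starved replicates 1, 2 and 3. A fit of the Type1 libraries alone called 1 gene. Of 13 Type1 genes named and called, Edem1, Rrm2, Sqle, Tcrg-C1 and Trgj1 kept their calls in each case. Hba-x, Hbb-bs, Hbb-bt, Serpina3f, Il2ra, Xbp1 and Hspa5 lost theirs without starved replicate 1 (adjusted p 0.0567 to 0.120), Hbb-bs, Serpina3f and Il2ra without starved replicate 2 (0.0522 to 0.0728) and Serpina3f, Il2ra, Xbp1 and Hspa5 without starved replicate 3 (0.0598 to 0.102). Without unstarved replicate 1 the calls of Hba-x, Hba-a1, Hbb-bs, Hbb-bt, Serpina3f, Il2ra, Xbp1 and Hspa5 were lost (0.0624 to 0.163), and without unstarved replicate 3 the same ones except Serpina3f (0.0633 to 0.121). The Type2 count was 1797, 986 and 2102 without unstarved replicates 1, 2 and 3 and 1333, 1219 and 1723 without starved replicates 1, 2 and 3, and of 13 named genes only Hbb-y lost its call (0.0526 without unstarved replicate 1, 0.0640 without unstarved replicate 2).

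Starved Type1 cells were compared with starved WT cells, which asks what the mutant line keeps or gains without cytokine. Of 26 DNA replication genes 14 rose in Type1. Ung, outside that list (ENSMUSG00000029591.14, chr 5 from 114130386 to 114139323) had 15.2 ± 2.54 CPM against 1.45 ± 0.228 in WT, a log2FC of 3.42 ± 0.54 (adjusted p = 0.0111). Cdc6, which loads the replicative helicase (ENSMUSG00000017499.15, chr 11 from 98907801 to 98923940), had 25.7 ± 5.18 against 4.14 ± 2.15 CPM (2.63 ± 0.42). Rmi2 of the Bloom complex (2.45 ± 0.39), the cyclins Ccne1 (2.19 ± 0.38) and Ccne2 (1.61 ± 0.24) and Rrm2 (1.51 ± 0.25) rose with them. Etv5, a transcription factor induced by ERK signalling (ENSMUSG00000013089.15, chr 16 from 22381309 to 22439719), rose by 2.92 ± 0.48, the ERK phosphatases Dusp6 and Dusp4 by 1.60 ± 0.26 and 1.27 ± 0.21, and the ERK inhibitor Spry4 by 2.83 ± 0.60. Other large rises were Nxpe5 (ENSMUSG00000047592.17, chr 5 from 138225898 to 138253363; 2.80 ± 0.32, adjusted p = 0.00134), Tcrg-C1 (2.73 ± 0.55) and Id1 (2.63 ± 0.43). Col7a1, a collagen (ENSMUSG00000025650.12, chr 9 from 108953586 to 108984875), fell (-1.40 ± 0.20, adjusted p = 0.00717), as did Usp54 (-1.31 ± 0.26), Map3k6 (-1.14 ± 0.22) and Six4 (-1.07 ± 0.20). Il10ra, a cytokine receptor chain (ENSMUSG00000032089.16, chr 9 from 45253837 to 45269149), and the noncoding 9930022D16Rik were chosen after their values were seen. Il10ra had 0 counts over the Type1 group against 169 over WT, at least 86.0-fold lower, and 9930022D16Rik had 0.157 against 3.31 CPM (log2FC -4.36).

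**Figure D1:**
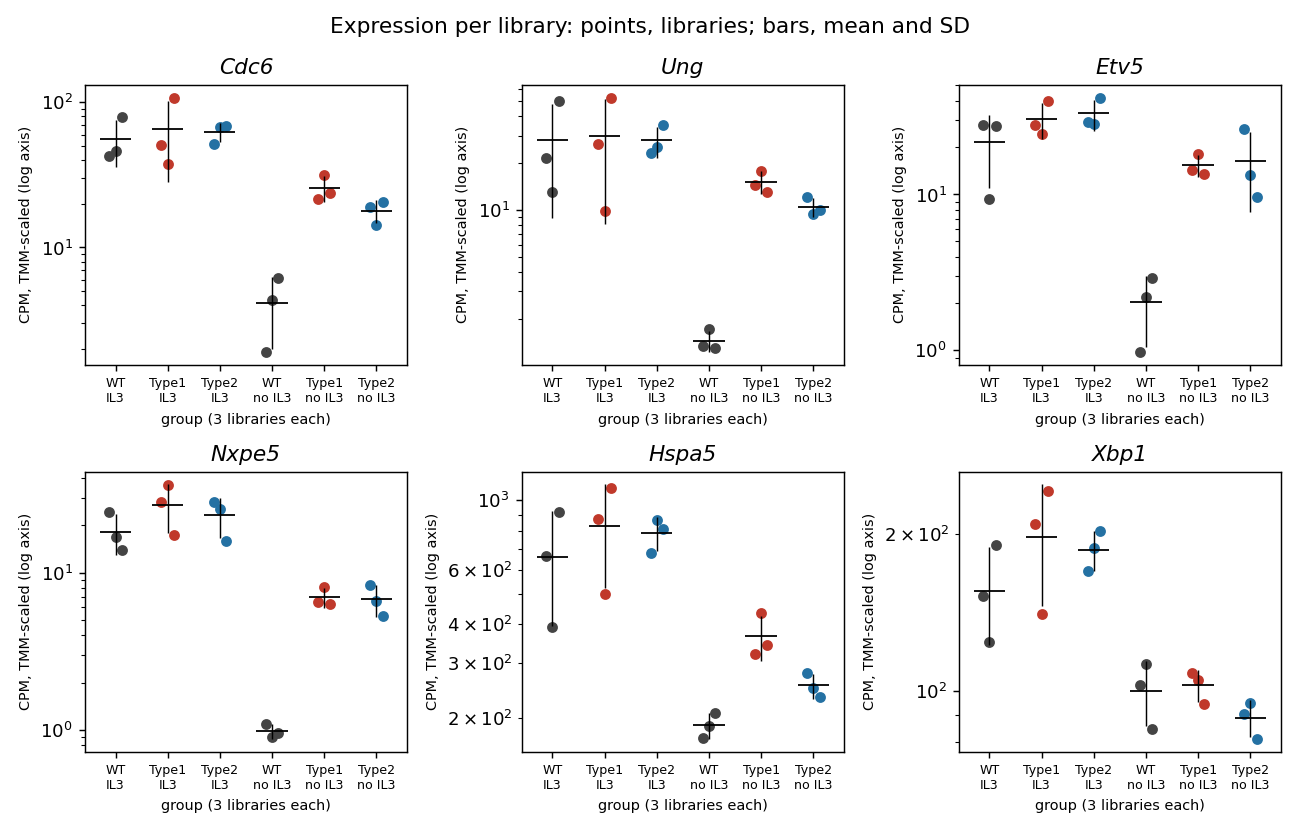
TMM-scaled CPM (log axis) of Cdc6, Ung, Etv5, Nxpe5, Hspa5 and Xbp1 in each library of the 6 calreticulin groups, with and without IL3 (x axis); points are libraries (n = 3 per group), and lines give the mean and SD. In starved WT cells Ung averaged 1.45 CPM and Nxpe5 0.982 CPM, against 15.2 and 6.95 CPM in starved Type1 cells, while Xbp1 averaged 100 and 103 CPM.

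In all, 108 genes changed between starved Type1 and WT cells (94 higher, 14 lower, 92 at least 2-fold), or 760 with the replicate block (571 higher, 189 lower), 983 by DESeq2 and 48 by limma-voom. All 26 DNA replication genes had a positive log2FC and 14 rose (25 adjusted over the list alone, median 1.35, camera adjusted p = 6.02e-39). Ribosome biogenesis had 24 of 24 genes positive and 1 rise, Nop56 (1.43 ± 0.27; 18 adjusted over the list alone, median 0.78, adjusted p = 2.9e-16). Cholesterol synthesis had 2 rises among 21, Sqle (1.02 ± 0.16) and Idi1 (1.29 ± 0.26; 10 adjusted over the list alone, median 0.52, adjusted p = 1.13e-08). ERK targets had 4 rises among 14 (5 rises and 1 fall adjusted over the list alone, median 0.72, adjusted p = 7.36e-05). In the following lists 0 members passed over all genes: mitosis (0 adjusted over the list alone, median 0.55, adjusted p = 6.77e-06), oxidative phosphorylation (4; 0.43, adjusted p = 2.46e-07), glycolysis (4; 0.39, adjusted p = 4.54e-04), cytosolic heat shock (5; 0.72, adjusted p = 2.53e-04) and autophagy and lysosome (0; -0.14, adjusted p = 0.0357). Hspd1, a mitochondrial chaperone of the heat shock list, had 1.49 ± 0.38 (adjusted p = 0.0833, and 0.0275 with the replicate block). Only 8 of the 12 members of that list were measured, without Hspa1a, Hspa1b, Bag3 and Hspb1. FOXO targets (median -0.48, adjusted p = 0.0679; -0.50 and 0.0422 with the replicate block) and p53 targets (-0.42, adjusted p = 0.125; -0.43 and 0.011 with the block), each with 0 members past the test and 0 adjusted over the list alone, were called with the block but not without it. With the block and an estimated correlation they were not called (adjusted p = 0.504 and 0.443). Leaving out a library also gave calls, for FOXO targets without Type1 starved replicate 1 (0.00758) or 2 (0.00958) or WT starved replicate 1 (0.0309), and for p53 targets without Type1 starved replicate 1 (0.0301) or 2 (0.0187) or WT starved replicate 3 (0.0226). With an estimated correlation all 12 list calls were lost (adjusted p from 0.175 to 0.703 with an estimated correlation). Over the same libraries, mitochondrial genes took 4.27% to 7.76% of counts in WT and 1.40% to 2.29% in Type1. The count of genes was 3 without Type1 starved replicate 2, 37 without Type1 starved replicate 1, 33 without WT starved replicate 2 and 171 without WT starved replicate 3. Of 22 named calls, those of Nxpe5 and 9930022D16Rik were kept in every case, and the 20 others were lost without Type1 starved replicate 2 (adjusted p 0.0546 to 0.219). Tcrg-C1, Usp54, Spry4, Nop56 and Idi1 were also lost without Type1 starved replicate 1 (0.0737 to 0.154), Map3k6, Six4 and Spry4 without Type1 replicate 3 (0.0540 to 0.0672), Map3k6, Spry4 and Idi1 without WT replicate 1 (0.0509 to 0.0678), Tcrg-C1, Ccne1, Usp54, Map3k6, Six4, Spry4, Nop56 and Idi1 without WT replicate 2 (0.0544 to 0.184), and Tcrg-C1, Six4 and Spry4 without WT replicate 3 (0.0638 to 0.109). The autophagy list was lost without WT replicate 1 (0.164) or 3 (0.0660) or Type1 replicate 3 (0.397).

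Of the unfolded protein response and survival, Xbp1, Ern1, Hspa5, Ssr1, Bcl2, Bcl2l11 and Pim1 did not pass the test between starved Type1 and WT cells without the replicate block. Xbp1 (ENSMUSG00000020484.18, chr 11 from 5520659 to 5525893), the transcription factor that IRE1 activates by splicing its RNA, stood at 103 ± 7.31 CPM in Type1 and 100 ± 14.4 in WT (log2FC 0.04 ± 0.19, adjusted p = 0.946). Gene counts do not separate the spliced form. Ern1, which encodes IRE1, had -0.50 ± 0.39 (0.553). Dnajb9, another XBP1 target, had 28.8, 27.1 and 22.5 CPM in Type1 starved replicates 1, 2 and 3, against 30.0, 37.2 and 25.5 CPM in WT. Hspa5 (ENSMUSG00000026864.13, chr 2 from 34771970 to 34777547) had 366 ± 60.3 against 189 ± 17.8 CPM (0.95 ± 0.28, adjusted p = 0.118), and Ssr1 0.78 ± 0.22 (0.105; 0.0387 with the replicate block). Among 28 XBP1 targets 22 had a positive log2FC and 0 passed (2 adjusted over the list alone), with a median of 0.24 that camera called higher (adjusted p = 0.0023; adjusted p = 0.535 with an estimated correlation). Without Type1 starved replicate 2 that median was 0.15. Among 14 ATF6 targets 13 were positive and 0 passed (2 adjusted over the list alone, median 0.48, adjusted p = 1.08e-04; adjusted p = 0.417 with an estimated correlation). Of 17 STAT5 targets 1, Id1, rose (1 adjusted over the list alone, median 0.11, mean 0.33, adjusted p = 0.0357; adjusted p = 0.65 with an estimated correlation). The STAT5 call was lost without WT starved replicate 1 (median 0.23, adjusted p = 0.0560) or 3 (0.13, adjusted p = 0.38) and without Type1 starved replicate 1 (0.11, adjusted p = 0.098) or 2 (-0.03, adjusted p = 0.0804). Bcl2 was at 629 ± 212 against 293 ± 81.0 CPM (1.10 ± 0.30, adjusted p = 0.0939; 0.00198 with the replicate block). Bcl2l11 had -1.05 ± 0.33 (0.133; 0.025 with the block) and Pim1 0.90 ± 0.31 (0.16; 0.0361 with the block).

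Starved Type2 cells were compared with the same starved WT libraries. Among the genes that the naming rule admits, Etv5 (3.01 ± 0.48, adjusted p = 0.0321), Nxpe5 (2.77 ± 0.32, 0.0016) and Rmi2 (2.17 ± 0.39, 0.0463) rose most, followed by AI506816 (1.67 ± 0.30), the heterochromatin protein Cbx5 (1.44 ± 0.25), Rrm2 (1.42 ± 0.25), Nmral1 (1.22 ± 0.21) and the receptor kinase Axl (ENSMUSG00000002602.16, chr 7 from 25757273 to 25788705, 1.15 ± 0.17). Il10ra and 9930022D16Rik, again chosen after their values were seen, were lower, Il10ra at least 77.6-fold with 0 counts in Type2 and 9930022D16Rik at 0.105 against 3.31 CPM (log2FC -4.91). Spry4 (3.27 ± 0.60, adjusted p = 0.0502; 0.00937 with the replicate block), Cdc6 (2.11 ± 0.41, 0.0633; 0.00584), Id1 (2.10 ± 0.42, 0.0719; 0.032), Dusp6 (1.36 ± 0.26, 0.0602; 0.0101), Dusp4 (1.11 ± 0.21, 0.051; 0.0155) and Sqle (0.85 ± 0.16, 0.0563; 0.0128) did not pass without the block but did with it, as with total library size, with no filter and by DESeq2. Cdc6 also passed without WT starved replicate 3 (0.0435). Hspa5 (0.43 ± 0.28, 0.705), Xbp1 (-0.17 ± 0.19, 0.853), Ern1 (-0.33 ± 0.39, 0.859), Bcl2 (0.60 ± 0.29, 0.612) and Bcl2l11 (-0.75 ± 0.33, 0.553) did not pass. All 26 DNA replication genes were positive and 1 rose (22 adjusted over the list alone, median 1.06, camera adjusted p = 7.77e-39), and 1 of 14 ERK targets rose (6 adjusted over the list alone, median 0.60, adjusted p = 1.32e-07). No member passed over all genes in ribosome biogenesis (1 adjusted over the list alone, median 0.49, adjusted p = 4.54e-12), mitosis (0; 0.59, adjusted p = 3.9e-08), cholesterol synthesis (2; 0.38, adjusted p = 3.2e-07), oxidative phosphorylation (0; 0.28, adjusted p = 4e-05) or glycolysis (0; 0.26, adjusted p = 0.00386). MHC class I presentation was lower, with 0 of 12 genes positive (0 rose or fell, 0 adjusted over the list alone, median -0.36, adjusted p = 0.00198), a call lost without Type2 starved replicate 3 (0.0558). Also lower, with 0 members past the test and 0 adjusted over the list alone, were autophagy and lysosome (2 of 21 positive, median -0.25, adjusted p = 0.00172), the interferon response (2 of 20, -0.30, 0.0311), FOXO targets (2 of 13, -0.43, 0.0422), p53 targets (3 of 13, -0.40, 0.044) and myeloid markers (2 of 11, -0.88, 0.0493). With an estimated correlation all 15 list calls between starved Type2 and WT cells were lost (adjusted p from 0.0869 to 0.649 with an estimated correlation). Myeloid markers were lost without Type2 starved replicate 1 (0.101), 2 (0.073) or 3 (0.0617) or WT starved replicate 1 (0.0702) or 2 (0.0647), and p53 targets without Type2 replicate 3 (0.841) or WT replicate 1 (0.0901) or 2 (0.359). The interferon response was lost without Type2 replicate 3 (0.315) or WT replicate 2 (0.0907), FOXO targets without WT replicate 3 (0.0953) and glycolysis without Type2 replicate 1 (0.0628). PERK-ATF4-CHOP targets (0 passed, 0 adjusted over the list alone, median -0.24, adjusted p = 0.277) were called with the replicate block (0.0166) and without Type2 replicate 2 (0.0439) or WT replicate 3 (0.00395). The pro-apoptotic BCL2 family (0 passed, 0 adjusted over the list alone, median -0.39, adjusted p = 0.0933) was called with the block (0.0222) and without Type2 replicate 2 (0.0328). With the block and an estimated correlation neither was called (adjusted p = 0.502 and 0.33). The PERK-ATF4-CHOP median was above 0 without WT replicate 2 or Type2 replicate 3.

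XBP1 targets did not pass between starved Type2 and WT cells (14 of 28 positive, 0 rose or fell, 0 adjusted over the list alone, median 0.01, adjusted p = 0.334), and without WT starved replicate 2 the median was 0.15. ATF6 targets did (0 rose or fell, 0 adjusted over the list alone, median 0.20, adjusted p = 0.0493), a call lost with the replicate block (0.127) and without WT starved replicate 3 (0.102) or Type2 starved replicate 1 (0.147) or 2 (0.122). STAT5 targets did as well (0 over all genes, 1 adjusted over the list alone, median 0.04, mean 0.35, adjusted p = 0.044), and this was lost with the block (0.0531), without WT starved replicate 1 (0.057) or 3 (0.56) and without Type2 starved replicate 1 (median -0.01, adjusted p = 0.321) or 2 (0.16). Without WT starved replicate 2 the STAT5 median was 0.32. Both calls were lost with an estimated correlation (adjusted p = 0.596 for ATF6 and 0.588 for STAT5 targets with an estimated correlation). In all, 15 genes changed (13 higher, 2 lower; 14 at least 2-fold), or 187 with the replicate block, 199 by DESeq2 and 2 by limma-voom. Mitochondrial genes took 4.27% to 7.76% of counts in these WT libraries and 1.60% to 2.81% in Type2. The count was 2 without Type2 starved replicate 1, 2 without replicate 2 and 3 without replicate 3, and 8, 3 and 27 without WT starved replicates 1, 2 and 3. Of 10 named calls those of Nxpe5 and 9930022D16Rik were kept in each case, though limma-voom did not call Nxpe5. Rmi2, AI506816, Cbx5, Rrm2, Nmral1, Axl and Il10ra were lost without Type2 replicate 3 (0.0566 to 0.142), and these with Etv5 without Type2 replicate 1 (0.151 to 0.249) or 2 (0.0649 to 0.102) or WT replicate 2 (0.0836 to 0.104). Etv5, Rmi2, AI506816, Cbx5, Rrm2 and Il10ra were lost without WT replicate 1 (0.0687 to 0.0722), and AI506816, Rrm2 and Nmral1 without WT replicate 3 (0.0621 to 0.0757).

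Of the 15 genes called in Type2, 13 were also called in Type1 in the same direction (11 higher, 2 lower), among them Etv5, Nxpe5, Rmi2, Cbx5, Rrm2, Nmral1, AI506816 and Axl. Independent lists of these sizes would share 0.0685 genes higher and 0.00157 lower, and 20 simulated pairs of unchanged groups against the same WT libraries shared 0. The simulations held no changed gene and no structure of replicate numbers, so few calls were possible and their 0 sets no level for 13. Of 25 splits of the starved libraries, the real one included, 3 gave at least 13, with a highest other of 19. With 1 library of each number per group 2 of 25 did, and with the replicate block only the real split reached its 159. Such splits can keep the WT libraries together and mix only Type1 with Type2, so they set no level for chance either. Across genes, which are not independent replicates, the correlation of both sets of log2FC was 0.798 against 0.533 in the simulations (0.515 to 0.564). The covariance was 0.262 against 0.124, a difference of 0.137. Part of the excess of the overlap and the correlation may come from the shared controls, which cannot be split into groups of 2. The shared count was 2 without Type2 starved replicate 1 and 27 without WT starved replicate 3.

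**Figure D2:**
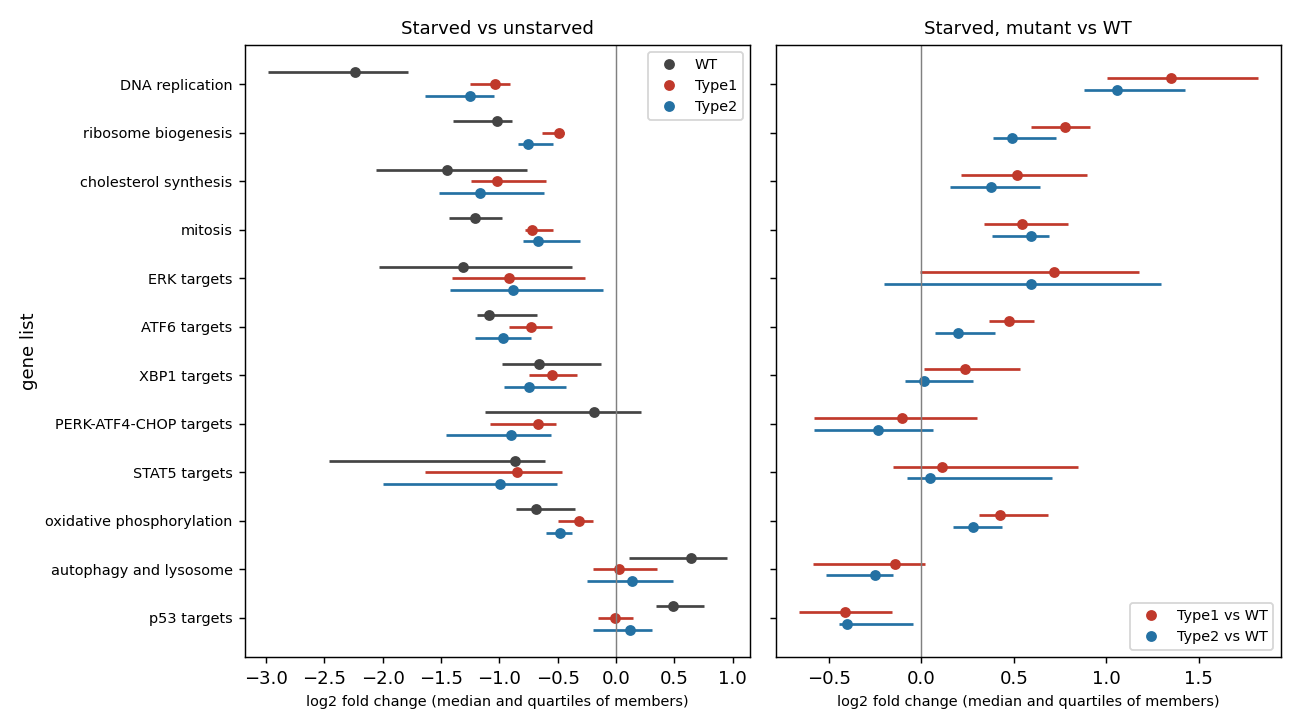
Median log2 fold change (points) and quartiles (lines) of 12 gene lists, for starved against unstarved cells of each genotype (left) and for starved Type1 and Type2 against starved WT cells (right), n = 3 libraries per group. DNA replication had medians of -2.24 in WT, -1.04 in Type1 and -1.25 in Type2 starvation, and of 1.35 and 1.06 in starved Type1 and Type2 against WT.

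Starved Type1 and Type2 cells were compared directly to ask what separates both mutants. Ptprtos, an antisense gene of Ptprt (ENSMUSG00000084919.1, chr 2 from 162390813 to 162393945), was the gene called (log2FC 6.99 ± 0.68, adjusted p = 0.00383); it was chosen after its values were seen. It had 332 counts over Type1 against 2 over Type2, a ratio of 150 (95% exact interval 41.2 to 1242 for counting error). The strand of the counting is not given, so reads of Ptprtos and of Ptprt could not be told apart. With the replicate block F13a1, a coagulation factor subunit also chosen after its values were seen, was called too. It had 0 counts over Type1 against 114 over Type2, at least 42.1-fold lower. XBP1 targets were higher in Type1 as a list, with 24 of 28 positive and none past the test (0 adjusted over the list alone, median 0.22, camera adjusted p = 3.57e-04; adjusted p = 0.863 with an estimated correlation). Without Type1 starved replicate 2 the median was 0.14. The individual values were 0.21 ± 0.19 for Xbp1, 0.55 ± 0.26 for Serp1 of the translocon and 0.53 ± 0.28 for Hspa5 (adjusted p = 0.999 each). ATF6 targets (14 of 14 positive, median 0.30, adjusted p = 3.57e-04), DNA replication (26 of 26; 0.27, adjusted p = 6.46e-05), ribosome biogenesis (21 of 24; 0.27, adjusted p = 9.12e-05) and cytosolic heat shock (7 of 8, among them Dnaja1 at 0.57 ± 0.23; 0.49, adjusted p = 5e-04) were higher as lists, each with 0 members past the test and 0 adjusted over the list alone. With an estimated correlation these calls were lost (adjusted p = 0.863 for each with an estimated correlation). In all, 8 of 26 lists were called, each higher in Type1. STAT5 targets were not called (0 rose or fell, 0 adjusted over the list alone, median 0.01, adjusted p = 0.637), but were without Type2 starved replicate 1 (0.18, adjusted p = 0.0146). Bcl2 had 0.50 ± 0.29. The count of genes was 1 (403 at unadjusted p under 0.05; 2 with the block; 4 by DESeq2 and 1 by limma-voom). Heat shock was lost without Type1 starved replicate 2 (adjusted p = 0.164), and ATF6 targets (0.0561) and ribosome biogenesis (0.0569) without Type2 starved replicate 3.

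With IL3 present, the lines were compared for differences that do not need starvation. In unstarved Type1 against WT cells 2 genes changed, both chosen after their values were seen: Ptprtos, with 334 counts against 0, at least 104-fold higher, and Sptbn5, a spectrin locus annotated as a processed transcript (ENSMUSG00000074899.4, chr 2 from 120041493 to 120085693; 6.13 ± 0.716 against 1.14 CPM, log2FC 2.42 ± 0.30, adjusted p = 0.00455). Against Type2 the same genes were called, Ptprtos at 5.86 ± 0.61 and Sptbn5 at 2.40 ± 0.30 (0.00518 each). Xbp1 had 0.34 ± 0.19 in Type1 and 0.26 ± 0.19 in Type2 against WT, Hspa5 0.32 ± 0.28 and 0.25 ± 0.28, Dusp6 0.77 ± 0.25 and 0.62 ± 0.25, Dusp4 0.75 ± 0.20 in Type1, Edem1 0.26 ± 0.12 in Type1 and Hbb-bt -2.38 ± 0.88 in Type2 (-0.68 without WT unstarved replicate 2). None of these passed (edgeR adjusted p = 1 for each). For Type2 against WT 0 genes passed edgeR's test, with 80 at unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom. The counts for Type1 were 140 at unadjusted p under 0.05 against WT and 70 against Type2. Sptbn5 lost its call against WT without WT unstarved replicate 1 (0.0831), 2 (0.0516) or 3 (0.0553), leaving 1 gene. Against Type2 both were lost without Type2 unstarved replicate 1 (0.0717) or 2 (0.0845), and a fit of only the Type1 and WT groups called 0.

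Of 26 lists 8 were called in unstarved Type1 and 8 in unstarved Type2 against WT, 7 higher and 1 lower in each, and 2 between Type1 and Type2. XBP1 targets were higher in unstarved Type1 (26 of 28 positive, median 0.20, camera adjusted p = 2.63e-04) and in unstarved Type2 (26 of 28; 0.15, adjusted p = 9.29e-05) than in WT, and ERK targets likewise (median 0.37, adjusted p = 0.00316, and 0.23, adjusted p = 3.99e-06). Interferon response genes were higher in Type1 (19 of 20 positive, median 0.43, adjusted p = 0.00328), and erythroid markers lower in Type2 (2 of 9 positive; -0.57, adjusted p = 7.48e-05). In each of these lists 0 members passed over all genes, and adjusted over the list alone 1 ERK target in Type1 and 0 in the others. Between Type1 and Type2 the XBP1 list was not called (0 passed, 0 adjusted over the list alone, median 0.04, adjusted p = 0.715). Interferon response (median 0.30, adjusted p = 0.00364; Irf1 at 0.33 ± 0.24) and MHC class I presentation (12 of 12 positive; 0.25, adjusted p = 8.95e-04; Psmb8 at 0.27 ± 0.19) were higher in Type1, with 0 members past the test and 0 adjusted over the list alone. These calls were lost with an estimated correlation (adjusted p from 0.111 to 0.954 with an estimated correlation). Each also depended on a library. Against WT in Type1, XBP1 targets were lost without Type1 unstarved replicate 1 (0.03, adjusted p = 0.0678) or WT unstarved replicate 2 (0.13, adjusted p = 0.16), ERK targets without the same libraries (0.25, adjusted p = 0.0548; 0.20, adjusted p = 0.503), and interferon without Type1 replicate 2 (-0.04, adjusted p = 0.611) or WT replicate 3 (0.16, adjusted p = 0.94). In Type2, XBP1 targets were lost without WT unstarved replicate 2 (0.08, adjusted p = 0.16) or Type2 replicate 2 (0.03, adjusted p = 0.304), and ERK targets (0.13, adjusted p = 0.101) and erythroid markers (0.00, adjusted p = 0.759) without WT replicate 2. WT unstarved replicate 2 had 32.4 CPM of Cish, against 122 and 148 CPM in the others of its group. In starved WT libraries Cish had 18.1 to 38.8 CPM. Hspa5 stood at 393 CPM in that library against 665 and 921 CPM, and Etv5 at 9.32 against 28.0 and 27.7 CPM. The XBP1, ERK and erythroid calls against WT thus cannot be told apart from the state of that library. Between the mutants, interferon was lost without Type1 replicate 1 (0.31, adjusted p = 0.113) or 2 (-0.09, adjusted p = 0.283) or Type2 replicate 3 (0.07, adjusted p = 0.35), and MHC class I without Type1 replicate 2 (0.07, adjusted p = 0.65) or Type2 replicate 3 (0.01, adjusted p = 0.985), while the XBP1 list was called without Type1 replicate 2 (0.14, adjusted p = 0.0045) or Type2 replicate 2 (0.16, adjusted p = 0.0137).

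Whether the starvation response itself differed was tested as an interaction. For Type1 against WT Rrm2 had a difference of 1.56 ± 0.35 (adjusted p = 0.69), Ccne2 1.47 ± 0.33 (0.69), Cdc6 2.41 ± 0.56 (0.806), Etv5 2.43 ± 0.63 (0.882), Hspa5 0.63 ± 0.40 and Xbp1 -0.30 ± 0.27 (0.975 each). For Type2 against WT Cdc6 had 1.95 ± 0.56, Etv5 2.40 ± 0.63, Spry4 2.77 ± 0.75, Hspa5 0.18 ± 0.40 and Xbp1 -0.43 ± 0.27, and for Type1 against Type2 Hspa5 had 0.45 ± 0.40 and Xbp1 0.13 ± 0.27 (adjusted p = 1 for each). By edgeR without the replicate block 0 genes passed in any of the 3 tests, with 718, 384 and 50 at unadjusted p under 0.05, 20, 2 and 0 by DESeq2 and 0 by limma-voom in each. DESeq2 called Rrm2, Ccne2 and Cdc6 (adjusted p = 0.0190 each) and Etv5 (0.0485) for Type1 against WT, where the alternatives gave these 4 genes adjusted p from 0.0105 to 1. As lists, DNA replication differed between Type1 and WT (median 1.21) and between Type2 and WT (0.93), with 0 members past the test. These calls were lost with an estimated correlation (adjusted p = 0.125 and 0.359 with an estimated correlation).

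In JAK2VF cells, with 1 library per condition and so no replicate check, the highest log2 ratios of starved to unstarved cells were those of Hba-a1 (5.24), Greb1 (5.02), Hbb-bs (4.86), Muc6 (4.74), Hbb-y (4.61), Hbb-bh1 (4.58), Hbb-bt (4.24) and the spectrin Spta1 (4.15). The lowest were Slfn2 (-3.42), Tcrg-C1 (-3.30), Cish (-2.87), Nupr1 (-2.64), Podnl1 (-2.51), Ifitm1 (-2.46), Prkcb (-2.39) and St6gal1 (-2.32). Xbp1 was at -0.87, Ern1 at 1.30, Hspa5 at -0.42, Pim1 at -1.28 and Bcl2l11 at 1.14. Medians were -0.82 for DNA replication, -0.82 for cholesterol synthesis, -0.69 for STAT5 targets, -1.09 for ERK targets and -0.75 for PERK-ATF4-CHOP targets, each at percentile 0 of 10000 random lists matched on expression. XBP1 targets had a median of -0.15 (percentile 58.9) and ATF6 targets -0.47 (0.94). Of 10004 genes 621 differed at least 2-fold (380 higher, 241 lower), and 658 of 10069 when scaled by total library size (471 higher, 187 lower). Across 9999 genes, which are not independent replicates, the ratios correlated with the log2FC of WT, Type1 and Type2 starvation at r = 0.740, 0.782 and 0.744.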

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

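The alternatives of the lists and the tests of a lasting difference between the lines and of the mitochondrial share were chosen only after the result was seen. The results here are lists whose response to IL3 withdrawal differed between genotypes by camera on the interaction, with positive medians where the fall was smaller or the rise larger in the genotype named before the other. Between Type1 and WT the median differences were 1.21 for DNA replication, 0.53 for mitosis, 0.53 for ribosome biogenesis, 0.45 for cholesterol synthesis, 0.60 for cytosolic heat shock, 0.31 for ATF6 targets, 0.30 for glycolysis, 0.29 for ERK targets and 0.29 for oxidative phosphorylation. They were -0.62 for the interferon response, -0.50 for p53 targets, -0.41 for FOXO targets and -0.28 for autophagy and lysosome. Between Type2 and WT they were 0.93 for DNA replication, 0.60 for mitosis, 0.34 for ribosome biogenesis, 0.32 for cholesterol synthesis, 0.25 for glycolysis, 0.16 for oxidative phosphorylation, 0.0735 for ERK targets and 1.70 for erythroid markers, the last at 0.032 (adjusted p = 0.996) without WT unstarved replicate 2. They were -0.50 for PERK-ATF4-CHOP targets, -0.54 for p53 targets, -0.32 for the interferon response, -0.26 for FOXO targets, -0.26 for autophagy and lysosome, -0.20 for MHC class I presentation and -0.68 for myeloid markers. Between Type1 and Type2 they were 0.17 for XBP1 targets, 0.24 for ATF6 targets, 0.28 for DNA replication, 0.18 for ribosome biogenesis, 0.15 for cholesterol synthesis, 0.16 for oxidative phosphorylation and 0.36 for cytosolic heat shock. With an estimated correlation each of these calls was lost (adjusted p from 0.125 to 0.927 with an estimated correlation).

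DNA replication, mitosis, ribosome biogenesis and cholesterol synthesis kept their calls against WT, in Type1 and in Type2, whichever library was left out. The other calls depended on single libraries. Between Type1 and WT, 8 calls were lost without Type1 unstarved replicate 2 (adjusted p 0.0634 to 0.4), 6 without WT unstarved replicate 3 (0.0535 to 0.478), 3 without Type1 starved replicate 3 (0.0809 to 0.609), 2 without Type1 starved replicate 2 (0.105 and 0.111), 2 without WT starved replicate 1 (0.0716), 2 without WT unstarved replicate 1 (0.0606 and 0.113), and 1 each without Type1 unstarved replicates 1 (0.187) and 3 (0.0757) and WT starved replicates 2 (0.185) and 3 (0.0844). Between Type2 and WT, 8 were lost without Type2 unstarved replicate 1 (0.0729 to 0.239), WT starved replicate 2 (0.062 to 0.808) or WT unstarved replicate 3 (0.303 to 0.658), and 7 without Type2 unstarved replicate 2 (0.0528 to 0.419). There 4 were lost without Type2 starved replicate 3 (0.16 to 0.621), 3 without Type2 unstarved replicate 3 (0.102 to 0.106), WT starved replicate 3 (0.113 to 0.384) or WT unstarved replicate 1 (0.0504 to 0.136), 2 without Type2 starved replicate 2 (0.24 and 0.417) or WT starved replicate 1 (0.0648), and 1 without Type2 starved replicate 1 (0.0661) or, for erythroid markers, WT unstarved replicate 2 (0.996). Between Type1 and Type2 all 7 were lost without Type1 unstarved replicate 2 (0.115 to 0.929), 6 without Type2 starved replicate 3 (0.0801 to 0.115), 3 without Type1 starved replicate 2 (0.0733 to 0.261), 2 without Type2 unstarved replicate 3 (0.114 and 0.188) and 1 each without Type1 starved replicate 1 (0.278) and Type2 unstarved replicate 2 (0.304).

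The DNA replication genes, higher in starved Type1 than in WT cells, had a median of 1.34 without WT starved replicate 2, the shallow library, against 1.35 with it, so that library alone does not produce it. Random lists matched on expression, transcript length and GC content had medians whose central 95% reached up to 0.290 over 1000 lists, with all 26 members matched, which argues against a length or GC trend. With IL3 the median between the same lines was 0.13, which argues against a difference of this size that lasts in the lines. RNA or cell quality stays open, since the lowest mitochondrial share in starved WT (4.27%) lay 1.98 percentage points above the highest in starved Type1 (2.29%), so that it cannot be told apart from the genotype. Also open is the candidate explanation that starved Type1 cells keep more cells in cycle than starved WT cells, which the counts do not test, and genotype and line remain confounded.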

How the results depend on the processing

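The tests with replicates 1 and 2 only, the block without WT starved replicate 2, the block with an estimated correlation, every alternative of lists other than XBP1 and STAT5 targets, and those of these 2 lists in Type1 and Type2 starvation and the interactions were chosen only after the result was seen. The count for WT starvation stayed within 1.5 times of 5270 in every setting run except without WT unstarved replicate 3. The calls and counts that moved are given here, and the cause was not tested. For starved Type1 against WT the count of 108 became 443 with total library size (429 higher, 14 lower), 397 with no filter, 373 with only the compared groups, 983 by DESeq2 and 48 by limma-voom. With replicates 1 and 2 only it was 2067, and leaving out single libraries gave 3 to 171. For starved Type2 against WT the count of 15 became 26 with median-of-ratios scaling, 53 with total size, 88 with no filter, 23 with the strict filter, 182 with replicates 1 and 2, 199 by DESeq2 and 2 by limma-voom, and 2 to 27 without single libraries. Their shared 13 became 24, 50, 78, 21, 177, 175 and 2 in the same order, and 2 to 27. Starved Type1 against Type2 had 2 with no filter, 0 with only the compared groups and 4 by DESeq2. Unstarved Type1 against WT had 1 with total size, 0 with only those groups, 6 by DESeq2 and 1 to 2 without single libraries. Unstarved Type2 against WT had 1 with no filter, 3 by DESeq2 and 1 by limma-voom. Unstarved Type1 against Type2 had 1 with total size, 1 with only those groups and 0 to 2 without single libraries. Starvation gave 3089 to 5278 genes in WT without single libraries. In Type1 it gave 1 with only those groups, 1338 with replicates 1 and 2, 1986 by DESeq2 and 152 to 2016 without single libraries, and in Type2 986 to 2102. The interaction of Type1 against WT had 1 gene with no filter, 77 with replicates 1 and 2 and 20 by DESeq2, and that of Type2 against WT 2 by DESeq2.

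The replicate block had 1 effect per number over all 18 libraries, the same in starved and unstarved cells, so no pairing within the starved libraries alone was fitted. In the comparisons where the numbers were taken as pairing the samples, it gave 760 genes in starved Type1 against WT, 187 in Type2 against WT, 159 shared, 2 in Type1 against Type2 and 4914 in Type2 starvation. Omitting WT starved replicate 2 as well gave 301, 133 and 109 shared. In WT and Type1 starvation, and so in the interactions that hold these groups, the numbers did not pair the samples. The block gave 9 genes in the interaction of Type1 against WT and 1 in that of Type2 against WT, both 0 with WT starved replicate 2 omitted. In the latter it ended the calls of oxidative phosphorylation (adjusted p = 0.0618) and erythroid markers (0.0806), and with an estimated correlation as well the lowest adjusted p of a list was 0.0536 over the 3 interactions. In starvation it gave 2375 genes in Type1, among them Bcl2l11 (1.28, adjusted p = 0.00276). In WT it added calls for Jak2 (0.55, 0.0125) and for p53 targets (0.57, 0.0105), megakaryocyte markers (0.77, 0.0168), the interferon response (0.46, 0.0331) and the pro-apoptotic BCL2 family (1.07, 0.0406), none of them called with an estimated correlation as well (0.255 to 0.459). Of 18 libraries 12 correlated best with a library of their own number, 6 of 6 for replicate 3. The misses thus all fell among replicates 1 and 2, for which a pairing was not shown. Other lists were called with the block alone, given here with their median without it and the adjusted p with it. They were glycolysis (0.20, 0.0417) in starved Type1 against Type2, and in unstarved Type1 against WT the anti-apoptotic BCL2 family (0.30, 0.0202), glycolysis (0.18, 0.0353) and autophagy and lysosome (0.13, 0.0353). In unstarved Type2 against WT they were STAT5 targets (0.069, 0.0447), MHC class I presentation (-0.083, 0.0414) and mast cell and basophil markers (-0.15, 0.0150), and in unstarved Type1 against Type2 glycolysis (0.12, 0.0369) and autophagy and lysosome (0.13, 0.0134). In Type2 starvation they were MHC class I presentation (0.35, 0.0326) and mast cell and basophil markers (1.28, 0.0300), and in the interaction of Type1 against WT PERK-ATF4-CHOP targets (-0.37, 0.00253), the pro-apoptotic BCL2 family (-0.46, 0.0214) and MHC class I presentation (-0.27, 0.0411). Without the block each had 0 members past the test and 0 adjusted over the list alone, except the mast cell and basophil list in Type2 starvation with 1 and 1. With the block and an estimated correlation 0 of 26 lists were called in any comparison. Beyond these and the blocked values given with the results, the block changed no other call among the genes named and the 26 lists.

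The XBP1 medians stayed the same with an estimated correlation but lost their calls, at 0.24 (adjusted p = 0.535) in starved Type1 against WT, 0.22 (0.863) in Type1 against Type2, 0.20 (0.854) and 0.15 (0.747) in unstarved Type1 and Type2 against WT and -0.66 (0.296) in WT starvation. With the replicate block added they were 0.24 (0.488), 0.22 (0.851), 0.20 (0.611), 0.14 (0.648) and -0.66 (0.288). Starved Type2 against WT passed with total size (0.18, adjusted p = 0.0371), and unstarved Type1 against Type2 turned to -0.043 (adjusted p = 0.0438) with replicates 1 and 2. Without single libraries the XBP1 median ran from 0.15 to 0.35, 0.014 to 0.15 and 0.14 to 0.28 in starved Type1 against WT, Type2 against WT and Type1 against Type2, 0.033 to 0.30 in unstarved Type1 against WT, 0.029 to 0.19 in Type2 against WT and -0.049 to 0.16 in Type1 against Type2. STAT5 targets in starved Type1 against WT had 0.11 (adjusted p = 0.65) with an estimated correlation, 0.11 (0.443) with the block as well, 0.073 (0.085) with the strict filter and 0.24 (0.118) with replicates 1 and 2. In Type2 against WT they had 0.044 (0.588) with an estimated correlation, 0.038 (0.459) with the block as well, 0.024 (0.0783) with the strict filter and 0.038 (0.0531) with the block alone, and in WT starvation -0.87 (0.259) with an estimated correlation and -0.87 (0.228) with the block as well. Without single libraries the STAT5 median ran from -0.033 to 0.23 in Type1 against WT, -0.0054 to 0.32 in Type2 against WT and -0.15 to 0.18 in Type1 against Type2. Other medians that changed sign were MHC class I presentation in the interaction of Type2 against WT, 0.0049 with total size, and, without single libraries, ribosome biogenesis (-0.040 to 0.50), cholesterol synthesis (-0.023 to 0.33) and oxidative phosphorylation (-0.058 to 0.33) in the interaction of Type1 against Type2. In unstarved cells the interferon response ran from -0.043 to 0.78 in Type1 against WT and -0.094 to 0.59 in Type1 against Type2, and erythroid markers from -0.95 to 0 in Type2 against WT. Among single genes named, limma-voom ended 19 calls and added 2, only the compared groups ended 28 and added 4, DESeq2 ended 2 and added 19, and no filter ended 0 and added 12. The strict filter left no value for Il10ra and Vpreb1. Depth limits WT starved replicate 2 most, and with 3 libraries per group the simulations, without the block, recovered 20.9% of 2-fold changes in starved Type1 against WT.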

Other observations

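The tests of the globin pattern, the use of the spread in the test of GC content, the test of GC content in the starved groups and the comparison of list medians and shared calls over splits that part all pairs of numbers were chosen only after the result was seen. Globin transcripts were summed per library, so that counted reads divided among copies add up again, whereas reads lost between copies stay missing. The sums, like the Slc4a1 values below, are CPM of total counts without TMM. They reached 1307 ± 722 CPM in starved WT cells against 163 ± 195 unstarved, 985 ± 593 against 42.3 ± 35.3 in Type1 and 1215 ± 530 against 33.2 ± 14.3 in Type2 (SD, n = 3 each). WT unstarved replicate 2 had 386 CPM, against 22.7 and 81.0 in the others of its group. In the single JAK2VF libraries the sums were 1826 CPM starved and 53.9 CPM unstarved. In JAK2VF the erythroid markers had a median log2 ratio of 4.24, MHC class I presentation 0.62, the interferon response 0.65 and autophagy and lysosome 0.39, each at percentile 100 of 10000 matched random lists. Megakaryocyte markers had 0.95 (percentile 99.99), glycolysis -0.80 (percentile 0), mitosis -0.57 (0.02) and the anti-apoptotic BCL2 family -0.63 (0.57).

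The group means of the summed globins were higher after starvation by at least 3.00 on the log2 scale in all 3 calreticulin genotypes, which counted reads that move between paralogs cannot give. Reads lost because they map to several places are not in the counts, so a change in their share was not tested. The value of 3.00 is that of WT, which was 4.66 without WT unstarved replicate 2 and 2.45 without WT starved replicate 1. RNA of red cells stays open: Slc4a1, an anion exchanger of red cell precursors, had at most 0.0432 CPM in unstarved and up to 0.755 CPM in starved libraries, and its level in red cells was not measured here. A rise of erythroid genes in these cells is a candidate explanation: Klf1 and Epor, an erythroid transcription factor and the erythropoietin receptor, had log2FC of 0.54 or more in all 3 genotypes. It stays open, since only Epor in Type2 passed the test (1.68, adjusted p = 0.0270), and no biological test separates it from other sources.

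Replicate 3 lay apart from replicates 1 and 2 in all 6 groups. The Spearman correlation across genes between transcript length and the difference of replicate 3 from the others ran from -0.070 to -0.147 (SD 0.026 over the groups). It was negative in all 6 groups and short of the 0.3 in size set for a cause. That argues against transcript length as the cause by itself, while a smaller part stays open. For GC content the correlation was -0.021, -0.053 and -0.096 in the unstarved groups (SD 0.096 over all 6), each short of the 0.3 in size that GC content as the cause in all 6 groups would need. In the starved groups it reached -0.280, so GC content stays open there as part of the cause. Ddit3, which encodes CHOP and was fixed by name, had 8.35, 7.53 and 7.74 CPM in replicate 3 of unstarved WT, Type1 and Type2. Replicates 1 and 2 had 44.0 to 128 CPM. In starved cells replicate 3 had 30.4, 13.2 and 14.2 CPM, against 39.1 to 149 CPM. Atf4, also fixed by name, was lower in replicate 3 of each group too, and the other PERK-ATF4-CHOP targets were not compared by replicate. A shared day or batch may be the source of the replicate 3 difference, but the labels name none, and no biological explanation was tested.

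The 6 libraries of a comparison have 10 splits, the real one included, which cannot give a share under 0.05. The counts of genes and the highest of the other splits were 108 and 0 in starved Type1 against WT, 15 and 0 in Type2 against WT, 1 and 0 in Type1 against Type2, 2 and 1811 in unstarved Type1 against WT, 0 and 1 in Type2 against WT, and 2 and 0 in Type1 against Type2. For starvation they were 5270, 891 and 3112 in WT, Type1 and Type2, with 0 in each for the other splits. Those other splits mixed starved and unstarved libraries on both sides, which adds the starvation effect to the spread within groups, so their 0 carries little weight. The split with 1811 genes put Type1 unstarved replicates 1 and 3 with WT unstarved replicate 3. Calling so many more genes, it points to a structure of the samples other than genotype. It holds both replicate 3 libraries on 1 side, but the other splits that did so called 0 genes, so that alone does not account for it. Its other side held WT and Type1 unstarved replicates 2. Cish was at 32.4 and 27.9 CPM in these, against 77.8 to 150 CPM in the other unstarved libraries and 14.05 to 38.8 CPM in starved ones. Tcrg-C1 was at 78.1 and 41.1 against 166 to 298 CPM unstarved, while Pim1 and Myc lay within the range of the others. Other splits with both replicates 2 on 1 side called 0 genes, and the cause was not tested. Among the 4 splits that part all 3 pairs of numbers, the highest other count was 0 in each comparison between genotypes and in Type2 starvation, with and without the replicate block. The 6 splits parting fewer pairs reached 1811 and 1 in unstarved Type1 and Type2 against WT and 0 in the other comparisons. The XBP1 medians and the highest of the other splits, in size, were 0.236 and 0.239, 0.012 and 0.11, and 0.22 and 0.21 in the starved comparisons of Type1 with WT, Type2 with WT and Type1 with Type2. They were 0.20 and 0.25, 0.15 and 0.22, and 0.042 and 0.31 in the unstarved ones, and 0.66 and 0.35 in WT starvation. For STAT5 targets they were 0.11 and 0.65, 0.044 and 0.87, and 0.0091 and 0.55 in the starved comparisons and 0.87 and 0.66 in WT starvation. Among the splits that part all 3 pairs, the highest other XBP1 medians were 0.17, 0.044 and 0.10 in the starved comparisons, in the same order, and 0.16, 0.22 and 0.31 in the unstarved ones, and those of STAT5 targets 0.14, 0.14 and 0.080 in the starved ones. The XBP1 splits parting fewer pairs thus reached higher in the 3 starved comparisons and in unstarved Type1 against WT. For the shared calls 3 of 25 splits gave at least 13, with a highest other of 19, which does not exclude chance. Among 25 splits with 1 library of each number in every group, 2 gave at least 13, with a highest other of 14, and with the replicate block 1, the real one, gave the real 159, with a highest other of 140. Both kinds of split can keep the WT libraries together and mix only Type1 with Type2, which retains the difference from WT. They therefore set no level of overlap expected by chance. For the interactions the real count was 0, which no split can fall below, so the splits test nothing there, and the highest other counts were 0, 1 and 697. The split with 697 again points to a structure of the samples.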
